A study of Drosophila melanogaster with 12 samples.

How the data were processed

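Polyadenylated RNA was sequenced from pools of 60 wing discs, with total RNA taken up in Trizol, treated with DNase and made into libraries with a stranded mRNA kit, per the labels' protocols. The authors deposited a single table of read counts, whole numbers per gene symbol and library, and no normalized values were used. Per the submitters' processing notes, the tools were TopHat2 2.0.9 and Bowtie2 2.1.0 for alignment, HTSeq for counting, and edgeR and DESeq, with the genome build dm6; the role of each is the usual one of the tool and is not spelled out. The annotation release and the strand setting of the counting are not given in the sources used here. If strand was ignored, reads of a gene and of an overlapping gene on the other strand could not be told apart, and reads of near-identical paralogs can be split or lost. Exons of 36 of the 152 named genes with a position share bases with another gene, 30 of them on the opposite strand and 9 by a large part, 28.3% to 82.7% of their exon bases, in the Ensembl annotation of BDGP6, the Ensembl name of dm6.

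Of the 17716 symbols, 13320 were matched to a current symbol of that annotation, 4215 through a synonym and 181 not at all; symbols are printed as deposited. The table also holds 2 blank lines, which carry no counts and were left out. Of 13838 symbols of protein-coding genes, 1511 are listed at 0 in all 12 libraries, RpS6 and usp among them, so a 0 can also come from the counting. Library totals were 21024017 to 42407447 counts, and no pair of replicates was identical.

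Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 9444, libraries were scaled by TMM, and a quasi-likelihood model was fitted over all 12 libraries with 1 coefficient per group, which leaves 8 residual degrees of freedom. The tests were N against WT, S against WT, NS against WT, NS against N, NS against S, and the interaction. The last asks whether NS differs from the sum of the separate N and S log2 changes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the SE of a log2 change is its size divided by the square root of the F statistic. CPM values are counts divided by the TMM-scaled library size. A gene was called beyond all groups when it was called in the same direction in NS against WT, N and S. The WT labels of replicates 2 and 3 were followed, and a fit with WT replicate 1 alone is among the alternatives.

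Before the data were examined 37 gene lists were fixed, of which 769 members were found in the table and 2 were not; the 35 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. With an estimated correlation 0 lists were called in each comparison, against 13, 14, 9, 9, 7 and 2 with the preset one in the order of tests above. Each camera call therefore rests on the preset value. The planned fry test of limma uses no preset correlation and asks whether a list changed at all, not whether it changed more than other genes. It kept 4, 11, 5, 2, 2 and 1 of these calls. The rule for named genes was fixed at the same time. It took the 8 highest and 8 lowest called genes per comparison with a mean of at least 5 CPM and no overlap between the groups' libraries. It also took up to 4 members per list with the smallest adjusted p, and 15 genes named in every comparison. brp, Hsp68, Lsp1beta, Hml, Ir87a, yellow-e and C15 as single levels were chosen after their values were seen where that rule does not name them.

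Whether replicate numbers pair the libraries was checked from the deviations of each library from its group mean. Only NS and S libraries of the same number deviated together in every pair (r = 0.456, 0.493 and 0.327 across genes), so the blocked value is given for NS against S where it changes a call or count. Over all 18 pairs of libraries with the same number in different groups the median r was −0.0196. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, library totals, no filter on low counts, fits of the compared groups alone, a replicate block, each library left out in turn, WT replicate 1 alone, and for lists an estimated correlation, fry, RLE and the block. Added after seeing the data were fits without NS replicate 3 and S replicate 3, log2 offsets corrected for exon length (lowess span 0.3), a block fit of NS and S alone, fits without the 3 libraries with most fat body RNA, and the list tests with each library left out. The gene, list and interaction tests were run on data simulated with the same changes in N and NS. For N against WT with 9318 genes, 36 of 100 genes changed 2-fold and 64 of 100 changed 4-fold were recovered, with 0 of wrong sign and 8 unchanged genes called. In the same data S against WT, the interaction and the genes beyond all groups held no change, and 0 genes were called in each. Recovery of a true interaction was not simulated.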

Results

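Messenger RNA was sequenced from wing imaginal discs, the larval epithelial sacs that form the adult wing and thorax, of third-instar Drosophila melanogaster larvae taken 6 days after egg laying. Each library came from a separate pool of 60 discs, and the 12 libraries fall into 4 groups of 3: a wild-type condition (WT), activated Notch made in part of the disc (N), loss of the polarity gene scribble (S), and activated Notch together with the scribble mutation scrib1 (NS). Activated Notch is the free intracellular part of the receptor, made from a transgene under the Gal4 system. S larvae were mutant throughout, carrying the scrib1 allele over a chromosomal deficiency in a background without the Gal4 driver, whereas NS larvae carried the driver, the transgene and scrib1. The genotype text of WT replicates 2 and 3 also lists the activated Notch transgene, although their condition reads wild type. The deposited table gives read counts for 17716 gene symbols. Library totals were 37721478, 38243080 and 39572136 counts in WT and 39596979, 36153792 and 42407447 in N. They were 39473260, 33356794 and 38456694 in S and 38048822, 21024017 and 40860792 in NS. Levels are given below in CPM, read counts scaled to library size, as mean ± SD over the 3 libraries of a group, and log2 fold changes as value ± SE. P-values measure the spread between these pools of discs. For each single gene named below as risen, fallen, higher or lower, all 3 libraries of the first group lay beyond all 3 of the second. For the 8 highest and 8 lowest genes of a comparison this was a condition of being named, so it adds no support to their calls. Called genes whose libraries overlapped are not named in this way. Chance gives such a separation for 10% of genes with 3 against 3, a share that holds only for genes not chosen by it or by the test.

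The targeted genes were examined first. Transcripts of scrib, which encodes a scaffold protein of the basolateral membrane (chromosome arm 3R, positions 26536350 to 26604051 in BDGP6), stood at 348, 448 and 370 CPM in WT replicates 1 to 3 and 511, 444 and 442 in N. They stood at 208, 200 and 129 CPM in S and 394, 434 and 87.2 in NS. The S to WT difference in scrib was −1.12 ± 0.455 on the log2 scale (edgeR adjusted p = 0.0978). It passed the edgeR test once NS replicate 3 was left out of the fit (adjusted p = 0.000792), and over all alternatives its adjusted p reached 0.501. In NS the scrib transcript was not shown to be lower: NS replicates 1 and 2 lay within the WT range, and the difference was −0.61 from N and −0.35 from WT (edgeR adjusted p = 0.373 and 0.587). These became −0.18 and 0.09 without NS replicate 3 and −0.05 and 0.10 with the length correction, so the mutation in NS rests on its genotype text. Transcripts of the Notch gene (N), to which reads of the transgene also count, stood at 652, 885 and 707 CPM in WT and 2236, 2016 and 2016 in N. They stood at 656, 604 and 287 CPM in S and 1602, 1458 and 501 in NS. The N to WT difference in the Notch transcript was 1.48 ± 0.408 (edgeR adjusted p = 0.0903). It passed without NS replicate 3 (edgeR adjusted p = 0.00789), with the length correction (0.000176) and with DESeq2 (0.00752), and over all alternatives its adjusted p reached 0.423. The NS to WT difference in the Notch transcript was 0.67 (edgeR adjusted p = 0.243), but 1.03 without NS replicate 3 (0.0219) and 1.17 with the length correction (9.77e-05). Both transcripts were lower in NS replicate 3 than in any WT library, so the library labelled NS replicate 3 does not show the raised Notch transcript of NS replicates 1 and 2. Long genes as a class were low in that library. Across 9379 genes, its log2 difference from NS replicates 1 and 2 had a Spearman correlation of −0.719 with exon length, with genes not being independent replicates. The corresponding correlation of S replicate 3 was −0.43.

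**Figure D1:**
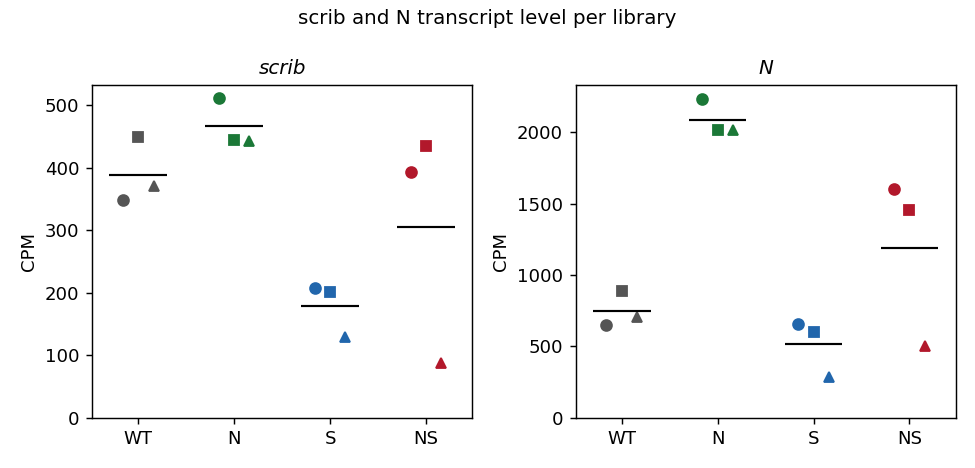
Transcript level of scrib (left) and N (right) in CPM for each library of WT, N, S and NS; circles, squares and triangles are replicates 1, 2 and 3, and bars are group means. NS replicate 3 lies at 87.2 CPM for scrib and 501 CPM for N, below the other NS libraries.

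**Figure D2:**
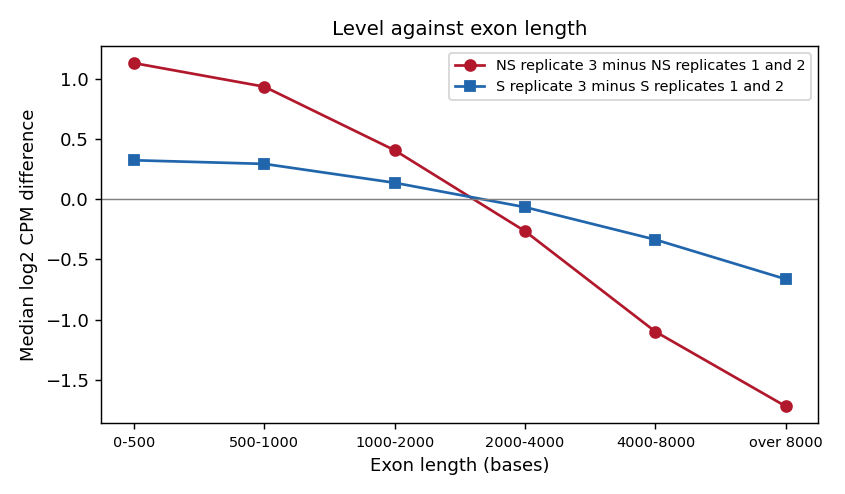
Median log2 CPM difference of NS replicate 3 from NS replicates 1 and 2, and of S replicate 3 from S replicates 1 and 2, for genes grouped by exon length in nucleotides. The NS replicate 3 difference runs from 1.13 in the shortest genes to −1.72 in the longest, and that of S replicate 3 from 0.323 to −0.664.

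N against WT asked how activated Notch changes the disc. Ilp8, which encodes the relaxin-like peptide by which disturbed discs delay metamorphosis, rose 68.1-fold, from 3.57 ± 2.16 to 243 ± 85.3 CPM (SD, n = 3 and 3). The Wnt ligand genes wg and Wnt6, active at the wing margin, rose 4.02-fold and 5.23-fold. ImpE2, a gene of disc eversion induced by the moulting hormone ecdysone, fell from 2833 ± 88.9 to 246 ± 134 CPM, and ImpE1, another ecdysone-inducible gene, and the nuclear receptor gene Eip78C were 6.56-fold and 15.3-fold lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 changes were 6.09 ± 0.609 for Ilp8 (adjusted p = 0.000653), 2.01 ± 0.245 for wg (0.0019), 2.39 ± 0.243 for Wnt6 (0.00071), −3.52 ± 0.45 for ImpE2 (0.00241) and −3.94 ± 0.444 for Eip78C (0.00126). The same test called 99 genes higher and 192 lower in N out of 9444, of which 66 and 168 differed at least 2-fold.

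Among the gene lists fixed before the data were examined, 21 Notch targets were tested in N against WT, and 5 rose and 2 fell (7 and 4 adjusted over the list alone). E(spl)m4-BFM, a small Notch-induced gene of the Enhancer of split complex, rose by 1.60 ± 0.224 (edgeR adjusted p = 0.00406), while the complex members E(spl)mbeta-HLH and E(spl)m7-HLH stood at −0.26 and −0.19 and did not pass. The Notch target list shifted upward against other genes (camera adjusted p = 0.0073; adjusted p = 0.73 with an estimated correlation). Its count of risen members was 2 without N replicate 1, 2 or 3 or WT replicate 1 and 3 without WT replicate 2 or 3. Without WT replicate 3 the list test missed the threshold (camera adjusted p = 0.613). Of 18 ecdysone response genes none rose and 5 fell (1 and 5 adjusted over the list alone), and the list shifted downward (camera adjusted p = 0.000903; adjusted p = 0.488 with an estimated correlation). Of 23 secreted signal genes 3 rose, Ilp8, Wnt6 and wg, and 1 fell (4 and 4 adjusted over the list alone). Of 18 basement membrane genes none rose and 3 fell (0 and 7 adjusted over the list alone), among them Timp, an inhibitor of matrix proteases, by −2.03 ± 0.249 (edgeR adjusted p = 0.0019) and the protease gene Mmp2 by −1.59 ± 0.229 (0.00442). That list shifted downward (camera adjusted p = 0.000208; adjusted p = 0.64 with an estimated correlation), with 5 members lower without NS replicate 1 and 6 without NS replicate 3. Exons of Timp overlap the gene Syn on the other strand over 15.7% of their bases, so its counts are uncertain as the strand setting of the counting is not given. None of 23 ribosome biogenesis genes passed by edgeR over all genes (3 rose and 0 fell adjusted over the list alone). Over all 9444 genes 1528 had an unadjusted p under 0.05, and DESeq2 called 317 higher and 502 lower. The ribosome biogenesis list shifted upward by a median of 0.34 (camera adjusted p = 4.13e-07; adjusted p = 0.488 with an estimated correlation). Of 22 genes of the stress kinase JNK and its targets, Ilp8 rose and 0 fell (1 and 1 adjusted over the list alone), and Mmp1, Ets21C and puc did not pass (−0.21, 1.25 and −0.02; edgeR adjusted p = 0.885, 0.155 and 0.987). Of 17 myoblast and muscle markers 0 rose and 1 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.00517; adjusted p = 0.278 with an estimated correlation), with a median of −0.849. That count was 0 without N replicate 1, 2 or 3 or WT replicate 2, 3 without S replicate 3 and 2 without WT replicate 3, and 1 rose and 7 fell without NS replicate 3. Of 13 haemocyte markers, genes of larval blood cells, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.00718, 0.111 without WT replicate 3; adjusted p = 0.64 with an estimated correlation), with a median of −1.06. The haemocyte count was 0 without any single library of N or WT. Of 7 tracheal markers 0 rose and 1 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0415; adjusted p = 0.73 with an estimated correlation), with a median of −0.346. The tracheal list test missed the threshold without N replicate 3 (0.111), S replicate 1, 2 or 3 (0.0544, 0.0517 and 0.0618) or WT replicate 2 or 3 (0.0926 and 0.0862). The tracheal count was 0 without N replicate 1, 2 or 3, S replicate 2 or WT replicate 1 or 2 and 3 without NS replicate 3. The 99 higher genes became 30, 26, 32, 22 and 28 without N replicate 1, 2 or 3 or WT replicate 1 or 2 and 343 without NS replicate 3. The 192 lower genes became 76, 57, 65, 80 and 70 without the first 5 of these libraries and 433 without NS replicate 3.

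S against WT asked what follows the loss of scribble, though the background of S also differs from that of WT. Ilp8 rose 142-fold to 505.5 ± 189 CPM (SD, n = 3 and 3), and the 3 genes for Unpaired cytokines, the ligands of the JAK/STAT pathway, rose together. Of these upd1 rose 7.39-fold, from 9.07 ± 0.303 to 67.0 ± 26.5 CPM, and upd3 rose 13.2-fold, from 2.57 ± 0.742 to 33.9 ± 23.7 CPM. The matrix protease gene Mmp1 rose 4.48-fold and the stress-induced transcription factor gene Ets21C 8.27-fold. ImpE2 fell from 2833 ± 88.9 to 1.34 ± 0.43 CPM, and nub, which marks the wing field, fell from 280 ± 11.3 to 74.4 ± 6.25 CPM. By edgeR's quasi-likelihood test the log2 changes were 7.15 ± 0.639 for Ilp8 (adjusted p = 4.8e-05), 2.89 ± 0.277 for upd1 (7.62e-05), 3.86 ± 0.676 for upd2 (0.00277), 3.72 ± 0.493 for upd3 (0.000493), 2.16 ± 0.336 for Mmp1 (0.00135) and −1.91 ± 0.238 for nub (0.000325). Exons of Ets21C overlap nAChRbeta3 on the other strand over 28.3% of their bases. The test called 1181 genes higher and 1000 lower in S. Of 16 apicobasal polarity genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), and 3 rose and 3 fell without NS replicate 3.

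Of 14 JAK/STAT genes 6 rose and 0 fell in S (6 and 0 adjusted over the list alone, camera adjusted p = 0.0666). Among them was chinmo, a transcriptional repressor gene, at 2.87 ± 0.559 (edgeR adjusted p = 0.00482). Of 22 genes of the JNK pathway 7 rose and 1 fell (8 and 1 adjusted over the list alone). Among them scaf, a JNK target, rose by 2.07 ± 0.319 (edgeR adjusted p = 0.00131) and wgn, a gene for a tumour necrosis factor receptor, fell by 1.58 on the log2 scale (0.000205). The JNK phosphatase gene puc stood at 0.74 and did not pass (edgeR adjusted p = 0.0581). The JNK list passed at a camera adjusted p of 0.0443 (adjusted p = 0.815 with an estimated correlation) and missed it without NS replicate 3 (0.0924), S replicate 3 (0.0934) or WT replicate 3 (0.134) and with the replicate block (0.057). Of 23 secreted signal genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00934; adjusted p = 0.793 with an estimated correlation). They include Pvf1, a PDGF- and VEGF-like ligand gene, at 2.66 ± 0.35 (edgeR adjusted p = 0.000472), and the morphogen gene hh fell at −1.08 ± 0.189 (0.00274). Without WT replicate 1 or WT replicate 2, 5 secreted signal genes rose.

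Notch targets went the other way in S: 2 of 21 rose and 9 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.0105; adjusted p = 0.815 with an estimated correlation). E(spl)mdelta-HLH fell by 3.45 on the log2 scale (edgeR adjusted p = 3.86e-05) and E(spl)m2-BFM by −2.44 ± 0.426 (0.00276), whereas wg stood at −0.24 (0.477). None of 38 wing patterning genes rose and 13 fell (0 and 13 adjusted over the list alone; camera adjusted p = 4.88e-05; adjusted p = 0.815 with an estimated correlation). Among them were inv, a posterior selector gene, at −1.51 ± 0.167 (edgeR adjusted p = 0.000167) and bs, the serum response factor gene of intervein cells, at −1.38 ± 0.158. Without NS replicate 3 the 13 became 22. Of 18 ecdysone response genes 2 rose and 8 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.000841; adjusted p = 0.793 with an estimated correlation). Eip78C was 75.6-fold lower at −6.24 ± 0.505 (edgeR adjusted p = 2.42e-05). Of 15 glycolysis genes 1 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0115, 0.0746 without S replicate 3 and 0.0657 with the length correction; adjusted p = 0.793 with an estimated correlation). The riser was ImpL3, the lactate dehydrogenase gene, at 16.3-fold from 19.3 to 313 CPM, while the aldolase gene Ald and the triose phosphate isomerase gene Tpi were 2.41-fold and 2.51-fold lower.

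Transcripts of other tissues varied between single libraries in S. Haemocyte markers rose in 5 of 13 cases and fell in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0372; adjusted p = 0.815 with an estimated correlation). Hml, the hemolectin gene, rose 6.05-fold and stood at 39.1, 110 and 166 CPM in S replicates 1 to 3 against at most 23.6 CPM in any other library. The haemocyte count was 3 without N replicate 1, S replicate 3 or WT replicate 1 and 2 without WT replicate 2, and the list test missed the threshold without NS replicate 3 (0.0924), S replicate 3 (0.0934) or WT replicate 2 (0.0574). Of 19 genes of the Toll and Imd immune pathways 4 rose and 1 fell (7 and 2 adjusted over the list alone; 9 rose without NS replicate 3). They include PGRP-SA, a peptidoglycan sensor gene, at 26-fold and the serpin gene nec at 8.62-fold (edgeR adjusted p = 0.000155 and 0.000142). RNA of the fat body, an organ that makes immune proteins and larval serum proteins, was highest in 3 libraries. The serum protein gene Lsp1beta stood at 4340 CPM in S replicate 1, 2080 in NS replicate 1 and 1100 in N replicate 2, and at 3.55 to 310 CPM in the other 9. Of 12 fat body markers 2 rose in S and 0 fell (2 and 0 adjusted over the list alone; 1 rose without S replicate 1 or 2 or WT replicate 2 or 3), including the fatty acid synthase gene FASN1 at 2.97 ± 0.44 (edgeR adjusted p = 0.00099). The synaptic gene brp stood at 73.6 CPM in S replicate 1 and at most 0.513 CPM elsewhere. The 3 neuronal markers of 10 that passed (4 adjusted over the list alone) became 0 without S replicate 1 or without WT replicate 1, 2 or 3, and 5 without NS replicate 3. The 1181 higher genes of S became 2268 without NS replicate 3 and 744, 602 and 559 without S replicate 2, WT replicate 1 and WT replicate 2. The 1000 lower genes became 1988, 633, 617 and 618 without these libraries. Without the 3 libraries with most fat body RNA 597 genes were higher and 534 lower.

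**Figure D3:**
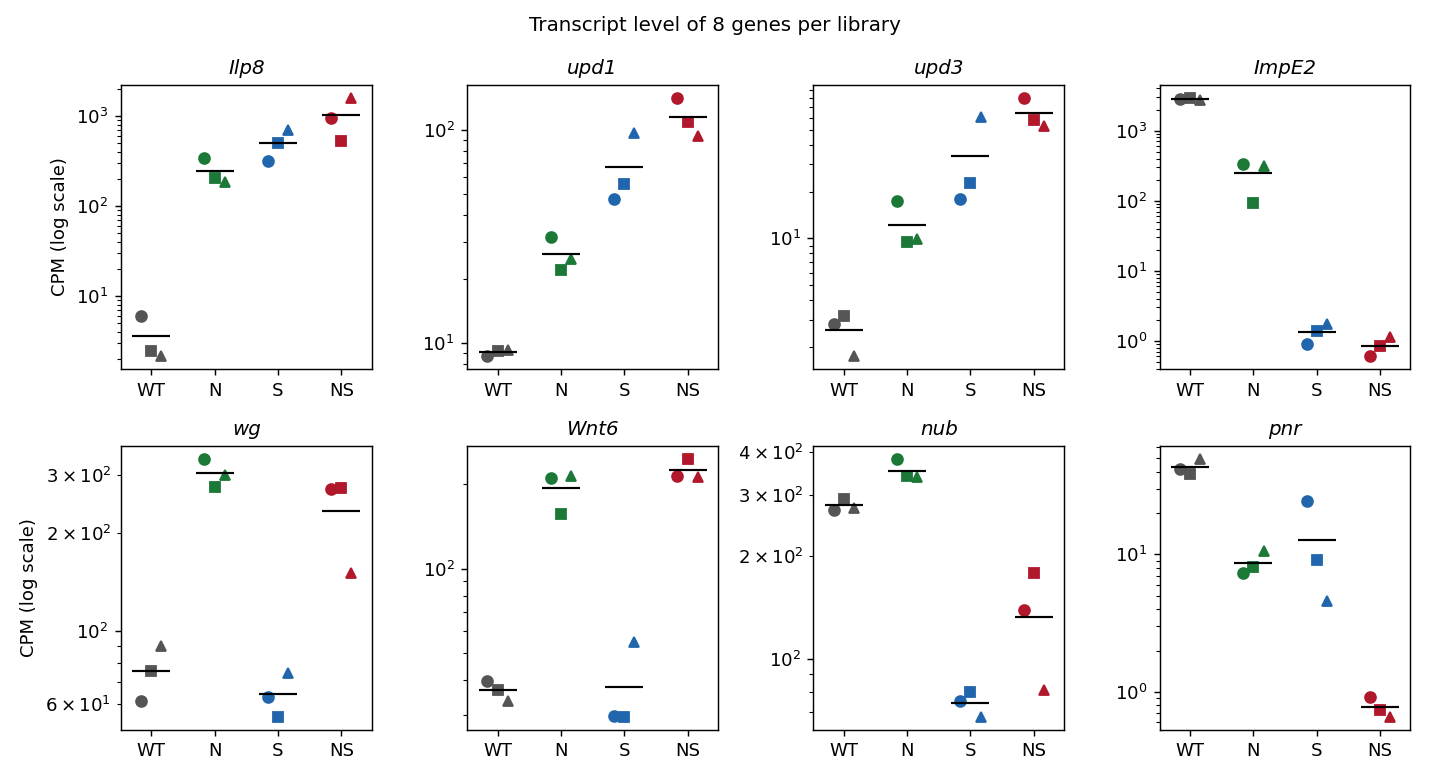
Transcript level in CPM (log axis) of Ilp8, upd1, upd3, ImpE2, wg, Wnt6, nub and pnr for each library of WT, N, S and NS; circles, squares and triangles are replicates 1, 2 and 3, and bars are arithmetic group means. Mean Ilp8 runs from 3.57 CPM in WT to 1024 CPM in NS, and mean ImpE2 from 2833 CPM in WT to 0.854 CPM in NS.

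NS against WT asked what both changes do together. Ilp8 rose 287-fold, to 1024 ± 535 CPM (SD, n = 3 and 3), and upd1, upd2 and upd3 rose 12.6-fold, 16.1-fold and 24.9-fold. wg and Wnt6 rose 3.07-fold and 6.07-fold. The cell death gene rpr rose 3.25-fold, from 26.6 ± 5.43 to 86.7 ± 21.5 CPM. ImpE2 fell to 0.854 ± 0.256 CPM, and pnr, the GATA factor gene that patterns the dorsal thorax, fell from 43.2 ± 5.94 to 0.774 ± 0.136 CPM. By edgeR's quasi-likelihood test the log2 changes were 8.16 ± 0.667 for Ilp8 (adjusted p = 3.27e-05), 3.66 ± 0.286 for upd1 (2.31e-05), 4.64 ± 0.512 for upd3 (0.000174), 1.62 ± 0.242 for wg (0.00112), 1.70 ± 0.248 for rpr (0.00096) and −5.79 ± 0.584 for pnr (9.83e-05). The test called 1308 genes higher and 986 lower in NS.

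Of 14 JAK/STAT genes 6 rose and 1 fell in NS (6 and 2 adjusted over the list alone), with chinmo at 3.44 ± 0.573 (edgeR adjusted p = 0.0021). Of 22 JNK genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), with Mmp1 at 1.40 ± 0.328 (edgeR adjusted p = 0.0124). Neither list passed the list test (camera adjusted p = 0.116 and 0.11). Of 21 Notch targets 6 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.585). E(spl)m4-BFM rose by 1.38 ± 0.223 (edgeR adjusted p = 0.0018) and edl, an antagonist gene of ETS factors, fell by −1.48 ± 0.249 (0.0022). The 4 that fell became 2 without N replicate 3 or WT replicate 1 and 1 without WT replicate 2. Of 38 wing patterning genes 2 rose and 17 fell (2 and 19 adjusted over the list alone; camera adjusted p = 1.59e-05; adjusted p = 0.85 with an estimated correlation). The list's median log2 change was −0.86, and −0.585 without NS replicate 3, where the list test gave 0.0386. Of 11 leg and haltere disc markers 1 rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.839 with an estimated correlation). They were led by al, a homeobox gene of the distal leg, at −2.78 ± 0.261 (edgeR adjusted p = 6.66e-05) and ss, an antennal and distal leg gene, at −4.21 ± 0.615 (0.000967). Of 18 ecdysone response genes 2 rose and 9 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.000206; adjusted p = 0.582 with an estimated correlation).

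Of 23 ribosome biogenesis genes 17 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 2.33e-07; adjusted p = 0.582 with an estimated correlation). Among them nclb and Non1 rose 2.03-fold and 2.19-fold (edgeR adjusted p = 0.00263 and 0.0027), and 10 rose without WT replicate 1 or WT replicate 2. Of 85 cytosolic ribosomal protein genes 43 rose and 0 fell (81 and 0 adjusted over the list alone; camera adjusted p = 7.99e-12; adjusted p = 0.85 with an estimated correlation), with a median log2 change of 0.761. These are short transcripts, with a median exon length of 909.5 nucleotides, and without NS replicate 3 the median was 0.338. The 43 became 14, 22 and 19 without N replicate 1, 2 or 3, 80 without NS replicate 1, 20, 8 and 21 without S replicate 1, 2 or 3, and 4 without WT replicate 1, 2 or 3. Of 15 glycolysis genes 1 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0263, 0.0617 without NS replicate 2 and 0.0755 with the length correction; adjusted p = 0.85 with an estimated correlation). ImpL3 was 10.7-fold higher and Tpi 2.6-fold lower, and the 7 became 4 without WT replicate 1. The 1308 higher genes of NS became 639 and 589 without WT replicates 1 and 2, and the 986 lower genes became 639 and 637.

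NS against N asked what the scrib1 mutation adds to activated Notch, though whether both groups were at the same developmental stage was not tested. upd1 rose 4.38-fold, from 26.2 ± 4.94 to 114.7 ± 24.6 CPM (SD, n = 3 and 3), and rpr rose 3.3-fold. Pvf1 rose 5.96-fold, scaf 4.22-fold, and ImpL3 8.78-fold. ImpE2 fell 287-fold from its level in N, pnr fell 11.1-fold, and nub fell 2.67-fold. By edgeR's quasi-likelihood test the log2 changes were 2.13 ± 0.268 for upd1 (adjusted p = 0.00113), 1.72 ± 0.248 for rpr (0.00217), 2.08 ± 0.32 for scaf (0.00308), 3.14 ± 0.434 for ImpL3 (0.00187), −8.17 ± 0.572 for ImpE2 (5.82e-05) and −1.42 ± 0.234 for nub (0.00443). The test called 396 genes higher and 341 lower in NS. wg and chinmo stood at −0.39 and 0.82 and did not pass (edgeR adjusted p = 0.288 and 0.309).

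None of 38 wing patterning genes rose and 11 fell in NS against N (0 and 17 adjusted over the list alone; camera adjusted p = 2.49e-10; adjusted p = 0.816 with an estimated correlation). They include eyg, a gene of the notum, at −2.82 ± 0.475 (edgeR adjusted p = 0.00488), and the 11 became 7 without N replicate 1 or 3. Of 11 leg and haltere disc markers 1 rose and 4 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00806; adjusted p = 0.816 with an estimated correlation). They include Dll, the distal limb selector gene, at −1.96 ± 0.333 (edgeR adjusted p = 0.00529), and 7 fell without S replicate 3. Of 22 JNK genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0437; adjusted p = 0.816 with an estimated correlation). That list test missed the threshold without N replicate 2 (0.0781), NS replicate 1 (0.21) or NS replicate 2 (0.188) and with the replicate block (0.0628), and 2 members rose without N replicate 2 or 3 and 8 without NS replicate 3. Of 18 ecdysone response genes 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.00806, 0.0603 with the length correction; adjusted p = 0.816 with an estimated correlation). Of 85 cytosolic ribosomal protein genes 3 rose and 0 fell (83 and 0 adjusted over the list alone; camera adjusted p = 1.61e-16; adjusted p = 0.816 with an estimated correlation). The 3 became 66 without NS replicate 1, 5 without NS replicate 3, 0 without N replicate 1 or 3, and 1 without any other library but NS replicate 2. Their median log2 change was 0.769, and 0.335 without NS replicate 3. The 396 higher genes became 180, 233 and 161 without N replicate 1, 2 or 3, and the 341 lower genes became 183 and 187 without N replicate 1 or 3.

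NS against S asked what activated Notch adds to the scrib1 mutation, and also sets larvae with the driver and transgenes against larvae of another background. vg, the wing selector gene and a direct Notch target, was 4.32-fold higher in NS, wg 3.62-fold and Wnt6 5.88-fold, the last from 38.0 to 224 CPM (n = 3 and 3). dpn, a Hairy-related repressor gene, was 6.63-fold higher. Timp was 10.2-fold lower and the collagen IV genes Cg25C and vkg were 3.75-fold and 3.65-fold lower. By edgeR's quasi-likelihood test the log2 changes were 2.11 ± 0.259 for vg (adjusted p = 0.00148), 1.86 ± 0.244 for wg (0.00213), 2.73 ± 0.367 for dpn (0.00246), −3.35 ± 0.263 for Timp (5.98e-05) and −1.91 ± 0.187 for Cg25C (0.000319). The test called 143 genes higher and 206 lower in NS than in S. In a fit of the 6 NS and S libraries alone with the replicate number as a block, 28 and 60 were called and wg missed the threshold (0.0619). Exons of dpn overlap an antisense RNA over 59.3% of their bases.

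Of 21 Notch targets 8 were higher and 1 lower in NS than in S (13 and 1 adjusted over the list alone; camera adjusted p = 3.66e-06; adjusted p = 0.853 with an estimated correlation). One was E(spl)mdelta-HLH at 2.30 ± 0.288 (edgeR adjusted p = 0.00162). In the block fit of NS and S alone the targets wg and nvy missed the threshold (edgeR adjusted p = 0.0619 and 0.0557). E(spl)mbeta-HLH and E(spl)m7-HLH passed it there (0.0152 and 0.0297). Of 18 basement membrane genes 0 were higher and 3 lower (0 and 4 adjusted over the list alone; camera adjusted p = 1.27e-06; adjusted p = 0.853 with an estimated correlation), and 5 were lower without NS replicate 3. Of 13 haemocyte markers 0 were higher and 2 lower (0 and 8 adjusted over the list alone; camera adjusted p = 1.27e-06; adjusted p = 0.853 with an estimated correlation). One was NimC1, a phagocytosis receptor gene of plasmatocytes, at −4.39 ± 0.672 (edgeR adjusted p = 0.00479), and 1 was lower without NS replicate 2, 3 without NS replicate 1 or 3 or S replicate 1. The other was Hml, which missed the threshold in the block fit of NS and S alone (edgeR adjusted p = 0.139). S replicates 2 and 3 were the libraries with most Hml RNA. Of 23 secreted signal genes 3 were higher and 5 lower (4 and 6 adjusted over the list alone), with the FGF genes pyr and ths at −1.68 ± 0.229 and −2.56 ± 0.411 (edgeR adjusted p = 0.00249 and 0.00661), and 3 were lower without S replicate 1 or 2. The cytokine and stress genes did not pass between NS and S by edgeR: upd1, upd3, Ilp8 and Mmp1 stood at 0.78, 0.92, 1.02 and −0.76 (adjusted p = 0.144, 0.329, 0.333 and 0.261). Of 14 JAK/STAT genes edgeR called 0 (0 higher and 1 lower adjusted over the list alone), while 1589 of all genes had an unadjusted p under 0.05 and DESeq2 called 399 higher and 496 lower in all. The eye pigment transporter gene w, a marker carried by many transgenes, was 15.3-fold higher in NS, at 440 ± 32.1 against 28.8 ± 9.25 CPM, and stood at 370 CPM in WT and 396 in N. The 143 higher genes became 367, 89, 75 and 395 without NS replicate 3, S replicate 1, S replicate 2 and S replicate 3. The 206 lower genes became 124, 127 and 337 without NS replicate 1, 2 and 3.

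In NS 18 genes were higher and 50 lower than in each of WT, N and S by edgeR. The strongest risers were Ir87a, an ionotropic receptor gene, at 192 ± 18.1 CPM against 0.19, 8.09 and 3.07 CPM in WT, N and S, and yellow-e, of the yellow family of cuticle and pigment proteins, at 937 ± 8.93 CPM against 12.8, 48.7 and 22.3 CPM. Act87E, a muscle actin gene whose reads can be shared with the other actin genes and are uncertain for that reason, stood at 231 ± 27.8 CPM against 18.4, 15.4 and 21.1 CPM. rpr was among the 18 but its difference from S missed the threshold without NS replicate 2, S replicate 1 or S replicate 2. Among the 50, pnr stood at −3.47 on the log2 scale against N, its nearest group, and the limb gene C15 at −3.25 against N. The 18 and 50 rest on the test of NS against S without the block. In the block fit of NS and S alone the differences of C15 and eyg from S missed the threshold (edgeR adjusted p = 0.066 and 0.124). The 18 became 10, 11 and 11 without N replicate 1, 2 or 3, 39 without NS replicate 3, and 9, 8 and 55 without S replicate 1, 2 or 3. The 50 became 27 and 30 without N replicate 1 or 3, 32 without NS replicate 1, 33, 33 and 86 without S replicate 1, 2 or 3, and 33 without WT replicate 1 or 2.

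**Figure D4:**
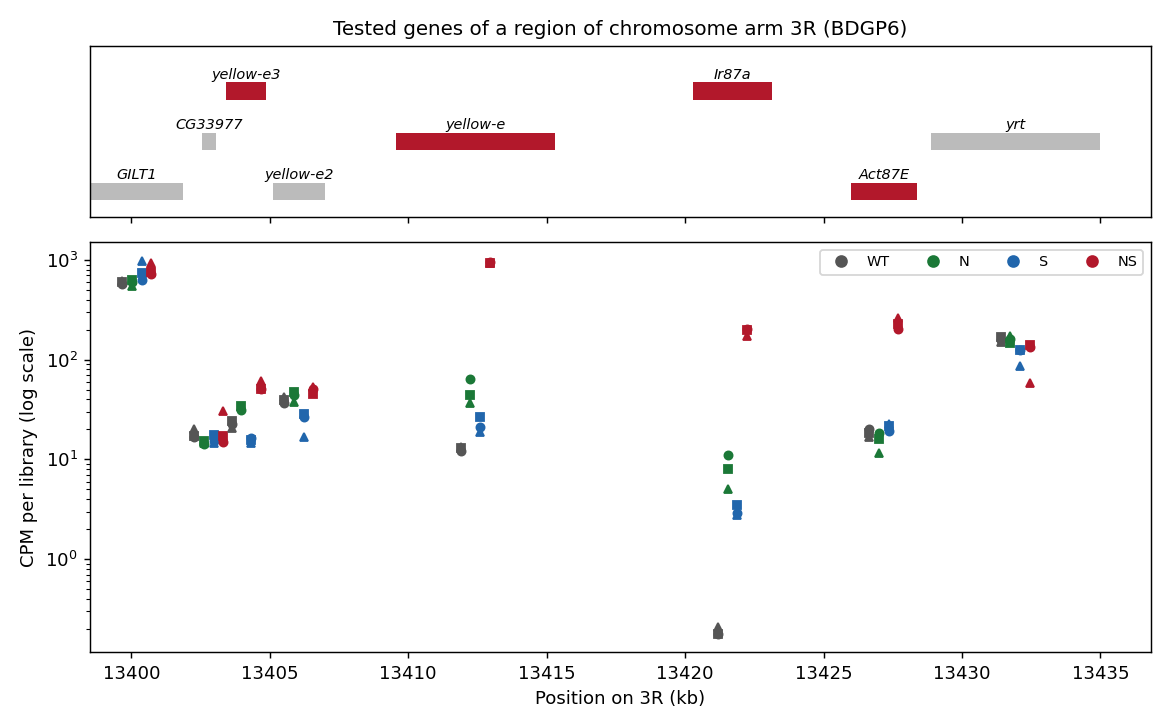
Tested genes of a stretch of chromosome arm 3R (BDGP6), drawn to scale, with the CPM of each library below. yellow-e, Ir87a and Act87E lie side by side and stand at 937, 192 and 231 CPM on average in NS.

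The same genes were often called in more than 1 comparison with WT. Of the 99 genes higher in N, 66 were also higher in S (12.4 for independent lists of these sizes) and 88 in NS (13.7), and of the 192 lower in N, 126 were lower in S (20.3) and 165 in NS (20). S and NS shared 765 higher and 618 lower genes (164 and 104 for independent lists). These comparisons use the same WT libraries. In 20 simulations all 12 libraries, WT included, were redrawn independently around the WT mean with no gene changed, and edgeR gave 0 shared calls. With no gene changed hardly any gene is called at all, so this count cannot show how many shared calls come from the shared controls. The draws also held no exon length trend. The simulated correlation of log2 changes across genes was 0.496, 0.5 and 0.491 for N with S, N with NS and S with NS. The observed correlations were 0.504, 0.649 and 0.735. The covariances were 0.732, 0.89 and 1.51 against simulated values of 0.158, 0.159 and 0.158, differences of 0.574, 0.731 and 1.35. As WT has 3 libraries it could not be split into parts of 2, and part of the excess over independent lists may come from the shared controls. All groups were taken 6 days after egg laying, and whether they had reached the same developmental stage was not tested. Stage therefore cannot be told apart from genotype in the comparisons with WT, nor in those of NS with N and with S.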

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

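None of the tests in this part was chosen after its result was seen. The interaction test asked whether the change from N to NS differs from the change from WT to S. It found 78 genes with NS above and 43 with NS below the sum of the separate log2 changes. A sum of log2 changes is a product of fold changes, so a gene below it can still have its highest level in NS. In 99 random regroupings of the 12 libraries into 4 groups of 3 the highest count was 8 against the real 121, and 1 of the 100 groupings, the real one, reached that count. Such regroupings mix the N and S differences into the spread between libraries, so they test only whether the groups differ at all, and chance stays open for the interaction itself. Of the 78 genes 74 were lower in S than in WT, 33 were lower in N and 31 in both. Of the 43 genes 34 were higher in S, 16 in N and 14 in both. Most of the called genes had thus changed in S and did not change by as much again from N to NS. The contrast itself holds the S and N differences from WT, so choosing genes by it favours such genes. These counts therefore describe the called genes and are no separate support for that reading. The background of S, without the driver and with a deficiency, also enters this contrast. Its part cannot be told apart from an interaction. The 78 became 41, 30 and 27 without N replicate 1, 2 or 3, 34, 45 and 176 without NS replicate 1, 2 or 3, 47, 45 and 247 without S replicate 1, 2 or 3, and 27 and 23 without WT replicate 1 or 2. The 43 became 18, 15 and 18, then 21, 19 and 101, then 24, 22 and 83, and 13 and 14 without the same libraries.

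The largest excesses of NS over the sum, on the log2 scale, were those of mthl8 (9.856), the non-coding bithoraxoid gene bxd (6.423), CG13053 (6.301), CG14395 (6.081), CG4382 (5.52), CG34247 (4.634), CG13737 (4.542) and PK2-R2 (4.248), a neuropeptide receptor gene. The 3 S libraries together held 2 counts of mthl8, 3 of CG14395 and 1 of CG34247, so the fitted values of these genes depend on the prior count and are no bound; mthl8 stood at 26.7, 25.7, 0.0179 and 19.6 CPM in WT, N, S and NS. The largest shortfalls were those of CR45682 (−7.625), CG11000 (−5.106), Ilp8 (−5.072), the glutathione transferase gene GstD3 (−4.512), CG12164 (−4.062), CG13215 (−3.752), Tdc2 (−3.683), an enzyme gene of tyramine synthesis, and Ptr (−3.139). Ilp8 was 68.1-fold higher in N, 142-fold in S and 287-fold in NS, each against WT. It fell short of the product of the N and S fold changes, while its mean level was highest in NS. CR45682 shares 74.0% of its exon bases with CG10657, and GstD3 has close paralogs, so the counts of both are uncertain. Leaving out 1 library ended the calls of bxd, CG14395, CG4382, CG34247, CG12164, CG13215 and Ptr for at least 9 of the 12 libraries each, and that of Tdc2 for WT replicates 1 and 2, but not those of mthl8, CG13053, CG13737, PK2-R2, CR45682, CG11000, Ilp8 or GstD3.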

How the results depend on the processing

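The fits without 2 or 3 libraries and those corrected for length were chosen after seeing the data. So were the block fit of NS and S alone and the list tests with each library left out. The rest were planned. Over the planned and added alternatives, 5810 of 6655 values of single named genes kept direction and call, 809 lost the call, 24 gained it and 12 turned; these leave out scrib and N, and 3 values of scrib turned as well. Counts below are higher then lower.

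With DESeq2 the counts were 317 and 502 in N against WT, 1516 lower in S against WT, 904 and 750 in NS against N, 399 and 496 in NS against S, 298 and 176 for the interaction, and 67 and 113 beyond all groups. In fits of the compared groups alone they were 547 and 773 in N against WT, 447 and 546 in NS against WT, 219 lower in NS against N, and 19 and 23 in NS against S. With library totals 786 genes were higher in NS than in WT. Without a filter 127 were lower in N than in WT, the interaction gave 48 and 27, and 11 were higher beyond all groups. With WT replicate 1 alone they were 9 and 109 in N, 268 and 416 in S, 243 and 398 in NS, 42 and 4 for the interaction, and 8 and 13 beyond all groups.

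With the replicate number as a block over all samples, 62 genes were higher in N than in WT and the interaction gave 48 and 25; the block fit of NS and S alone gave 28 and 60. Of the named genes of NS against S, 12 of 45 values lost the call under it and 2 gained it. Those lost by edgeR were wg and Hsp70Bb (adjusted p = 0.0619 each), nvy (0.0557), Wnt10 (0.0631), C15 (0.066), aos (0.068), stumps (0.0899), emc (0.0904), bxd (0.103), eyg (0.124), Hml (0.139) and Syn (0.233), and those gained were E(spl)mbeta-HLH (0.0152) and E(spl)m7-HLH (0.0297).

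Without NS replicate 3 and S replicate 3 they were 599 and 867 in N, 2245 and 2312 in S, 1611 lower in NS against WT, 844 and 792 in NS against N, 745 and 523 in NS against S, 598 and 297 for the interaction, and 114 and 146 beyond all groups. With the length correction they were 295 and 502 in N, 1812 and 1766 in S, 1569 lower in NS against WT, 777 and 743 in NS against N, 310 and 468 in NS against S, 204 and 137 for the interaction, and 55 and 110 beyond all groups. Without the 3 libraries with most fat body RNA they were 19 and 51 in N, 597 and 534 in S, 831 and 595 in NS, 139 and 155 in NS against N, 30 and 42 in NS against S, 7 and 3 for the interaction, and 5 and 9 beyond all groups, with fewer samples in the fit.

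With each library left out in turn, counts ran from 22 to 343 higher and 57 to 433 lower in N, 559 to 2268 and 617 to 1988 in S, 589 to 1462 and 637 to 1177 in NS, 161 to 502 and 183 to 479 in NS against N, 75 to 395 and 124 to 337 in NS against S, 23 to 247 and 13 to 101 for the interaction, and 8 to 55 and 27 to 86 beyond all groups. Without NS replicate 3, 99, 192, 1180 and 1000 of the genes called higher and lower in N and then in S were kept. In the comparisons that hold NS replicate 3 itself, 1011 of 1308 higher and 883 of 986 lower genes were kept in NS against WT, 322 of 396 and 304 of 341 in NS against N, 135 of 143 and 182 of 206 in NS against S, and 75 of 78 and 43 of 43 for the interaction. NS replicate 3 is in neither group of N against WT or S against WT, so it enters those counts only through the joint fit of all 12 libraries. For the 85 ribosomal protein genes in S against WT the median log2 change was 0.519 with and without it, while 3 and 78 were called higher. The gain in calls there thus came from the joint fit and not from larger changes. The cause of the other changes was not tested, and fits that leave out a library also hold fewer samples.

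Among single genes, the values that turned were not called. scrib in NS against WT was 0.0855 without NS replicate 3, 0.0799 without both length-trend libraries and 0.103 with the length correction, and −0.69 at the other end without NS replicate 2. E(spl)m7-HLH in N was 0.107 and 0.181 without WT replicate 1 or 2 and −0.668 without WT replicate 3, and wg in S was 0.0806 with WT replicate 1 alone. ct in S was 0.126 without S replicate 3, 0.00344 without WT replicate 2, 0.123 without both length-trend libraries and 0.118 with the length correction, and −0.581 without S replicate 1. In NS against S, upd2 was −0.00277, −0.234, −0.144 and −0.377 without NS replicate 1, S replicate 1, S replicate 2 and the 3 fat body libraries and 1.21 without S replicate 3, and Ets21C was −0.0503 without the 3 fat body libraries. An exception is the ribosomal protein list of NS against S, called upward with all libraries (adjusted p = 0.00733) and downward without NS replicate 3 (0.000168). It was not called with an estimated correlation (adjusted p = 0.931), with the length correction (0.189) or with fry (0.78). Its adjusted p with each other library left out ran from 2.05e-09 without NS replicate 1 to 0.0964 without S replicate 1.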

Other observations

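Of the tests in this part, those of the length trend, of another group for NS replicate 3, of the ribosomal protein genes and of the 3R genes were chosen only after the result was seen. Markers of the germline, a tissue outside the disc, were among the lists fixed in advance. Of 9 tested germline markers 3 rose in N, 6 in S and 5 in NS, and 0 fell (4, 6 and 5 adjusted over the list alone; camera adjusted p = 0.000208, 0.0115 and 0.00482; adjusted p = 0.101, 0.618 and 0.402 with an estimated correlation). krimp, a gene of the piRNA machinery, rose by 1.63 ± 0.233 in N (edgeR adjusted p = 0.0042), and nos, a translational repressor gene of germ cells, by 3.11 ± 0.449 in S and 2.50 ± 0.444 in NS (0.0029 in NS). Counts of nos summed over the 3 libraries of a group were 18, 52, 143 and 78 in WT, N, S and NS, so its level was low throughout. The 3 risers of N became 1 without N replicate 1 or WT replicate 2. Of 15 heat shock genes 1 rose and 6 fell in S (1 and 6 adjusted over the list alone), with the small chaperone gene Hsp27 6.53-fold lower (edgeR adjusted p = 6.91e-05), while Hsp68, the inducible chaperone gene, varied from 4.35 to 266 CPM within WT. The list shifted downward in S (camera adjusted p = 0.0372, and 0.815 with an estimated correlation). That test missed the threshold without NS replicate 3 (0.0924), WT replicate 1 (0.0686) or WT replicate 2 (0.103) and with the length correction (0.085). The heat shock list also shifted downward in N (camera adjusted p = 0.00245, and 0.676 with an estimated correlation). It shifted upward in the interaction (camera adjusted p = 0.00854, 0.91 with an estimated correlation and 0.0567 with the length correction).

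NS replicate 3 stood apart from NS replicates 1 and 2. Its difference from them followed exon length (Spearman −0.719 across genes), which is consistent with loss of long transcripts or a bias of that library. A wrong label is argued against, since over 104 genes called in NS replicates 1 and 2 against each other group it kept a median share of 0.876 of their difference. Of the 104 genes 77 kept a share over 0.5, and the length trend also enters these shares. The ribosomal protein genes kept 0.444 of their median rise in NS without it, a share between the bounds set for a trend in length and for a rise in NS, so the trend could account for part of the rise. As the whole cause it is argued against, since 35 of 85 were still higher without that library and 31 higher and 1 lower in the length-corrected fit of all libraries (camera adjusted p = 5.15e-10 and 5.77e-09). With all libraries the list had an adjusted p = 0.85 with an estimated correlation, and its 43 higher genes became 4 without WT replicate 1, 2 or 3, so the rise itself is not firm. In S against WT the same 85 genes had a median of 0.519 (camera adjusted p = 1.27e-06, and 0.834 with an estimated correlation). There 3 were higher with all libraries and 78 without NS replicate 3. No biological explanation was tested for the rise in NS or in S.

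4 of the 18 genes higher in NS than in each other group, yellow-e3, yellow-e, Ir87a and Act87E, lie within 24953 bp of chromosome arm 3R (13403423 to 13428375, BDGP6). In 10000 draws of 18 tested genes 0 had 4 in a window as short. The window and the number 4 were taken from the genes observed, and the draws treat neighbouring genes as independent. They therefore speak only against random placement of independent genes, not against neighbours that vary together. A change carried by the scrib mutant chromosome of NS alone would leave N as WT there, yet 3 of the 4 genes were higher in N than in WT: yellow-e3 at 0.57, yellow-e at 1.92 and Ir87a at 5.39 (edgeR adjusted p = 0.0246, 0.00101 and 4.87e-05), while Act87E stood at −0.26, so this test leaves it open as only all 4 would exclude it. By its genotype text S also carries the FRT82B scrib1 chromosome, and there Ir87a and yellow-e were higher than in WT by 3.99 and 0.80 (edgeR adjusted p = 2.13e-05 and 0.0181), but its libraries stood at 19.1 to 22.6 CPM for Act87E, 18.9 to 26.9 for yellow-e and 2.79 to 3.50 for Ir87a against at least 205, 929 and 172 in NS, which argues against that chromosome by itself as the cause of the NS level. yellow-e2, between yellow-e3 and yellow-e, was not called in NS against N (0.21, edgeR adjusted p = 0.444) or WT (0.33, 0.199), but was higher in NS than in S (1.05, 0.0101).

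The genotype text of WT replicates 2 and 3 lists the activated Notch transgene. In a fit with WT replicate 1 alone, 1 Notch target, wg, was called higher in N, and WT replicates 2 and 3 lay 0.428 above WT replicate 1 against 2.3 for N, a share of 0.186. Over all 86 genes called in that fit the median was 1.23 against 3.82, a share of 0.322, but genes chosen by a difference from WT replicate 1 lean toward N in any other library. Transcripts of the Notch gene, to which the transgene's reads count, stood at 885 and 707 CPM in WT replicates 2 and 3 against 652 in WT replicate 1 and 2016 to 2236 in N, nearer to what the WT labels say. With 1 reference library these values do not decide it: a slip in the text and a weakly active transgene both stay open, and such a share could also come from the spread between pools.

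The 10 tested genes nearest to scrib had a median log2 change of −1.18 in S against WT, and 6 of them were lower there; 10 of 6722 windows of 10 neighbouring genes had a median as low. Tl, a gene of the Toll and Imd list, was among the 6 (−1.32, edgeR adjusted p = 0.0298). The deficiency of S may remove 1 copy of these 10 genes. In NS against N they stood at a median of −0.303, beyond the bound set for that test, so the test leaves it open. That median was within the bound without NS replicate 3 (−0.0189) and with the length correction (−0.143). With the length correction the median in S against WT was −1.07.

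For the comparisons of 2 groups the 10 splits of 6 libraries are too few for a share under 0.05. In fits of 6 libraries the real split called 1320 genes for N and WT, 2819 for S and WT, 993 for NS and WT, 497 for NS and N, and 42 for NS and S, against at most 0, 0, 0, 17 and 0 in another split; in each case 1 split, the real one, reached its count. For the genes beyond all groups 1 of 100 groupings of the 12 libraries reached 68, the next highest giving 0. Such groupings mix the differences between groups into the spread within them, so this tests only whether the groups differ at all and leaves open whether chance put single genes beyond all groups. In S 91 genes were higher and 87 lower than in each other group, CG14692 standing at 225 ± 22.8 CPM in S and at most 0.208 CPM on average elsewhere.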
